A study of Drosophila melanogaster with 3 samples.

How the data were processed

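The samples were 3 biological replicates of 1 group, whole Drosophila melanogaster embryos aged 0 to 24 h from a transgenic line that carries knrl fused to enhanced GFP. Knrl (knirps-like) is a transcription factor of the nuclear receptor family and a close relative of the gap protein Knirps. Chromatin was sheared by sonication to a size range of 200 to 800 (unit not given in the labels) and precipitated with an antibody against GFP, per the labels. The replicate numbers were taken from the labels. There was no second group, so no groups were compared, and no input or tag-free control was analysed here.

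The authors deposited 14 peak lists on the dm6 build. Each replicate has a ranked list and a thresholded list, and 4 ranked and 4 thresholded lists cover the whole series, 1 of the latter named conservative. Per the deposited text files, each replicate's lists derive from that replicate's alignments and a common file, and the series lists derive from the alignments of all 3 replicates. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of a peak is the peak strength as the authors' caller gave it, and was used only to rank or describe peaks within a list, apart from the correlation between replicates across peaks. The −log10 value of each ranked peak is the deposited −log10 of the irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between lists, and it is capped at 5. Every thresholded list was found to be a subset of exactly 1 ranked list, with all −log10 IDR values at 2 or more, that is, an IDR of at most 0.01. Read depth is unknown because the lists hold no read counts. Confidence intervals on shares of peaks or genes are 95% Wilson intervals and cover counting error only.

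Coordinates were read on dm6, the same assembly as Release 6 of the reference sequence, and are given counted from 1. Genes came from Ensembl release 115. Summits on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X were analysed, and those on Y and on unplaced sequences were left out. This kept 3663 of the 3710 conservative peaks, 2875 of 2941 in replicate 1, 3030 of 3051 in replicate 2 and 3382 of 3388 in replicate 3. Some peaks of a list overlap each other: the 3663 conservative peaks form 3224 separate regions, so peaks are not fully independent.

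The conservative list was the main peak set, and the 3 replicate lists gave means and SDs. Which replicates each series-wide list compares is not given in the sources used here, so these lists were chosen by name and length. Overlap between replicates (at least 1 bp) was compared with 100 random placements of the second list. Promoter summits lay within 500 bp of an annotated transcription start site (TSS) and were compared with 1000 random placements on the same arm by a two-sided permutation test. A gene counted as bound when a summit lay in its body or within 2 kb of it. The bound members of 23 gene lists were compared with 10000 random lists of protein-coding genes matched on gene length in 20 bins, by a two-sided permutation test with Benjamini-Hochberg adjustment over the lists. Random lists drew genes singly and did not keep neighbouring genes together. Where members of a list lie side by side, the permutation p treats them as independent. Of 606 list members, 605 matched an annotated symbol, after 10 outdated symbols had been updated. Words were sought on both strands within 100 bp of each summit and in a window of the same size centred 1000 bp to the lower-coordinate side. Their shares were compared by a two-sided exact McNemar test, adjusted over the 9 fixed words or over all 8192 words of 7 bases. Trends with peak signal were tested by Spearman correlation with 100000 permutations. Calls used an adjusted p under 0.05. For promoters of housekeeping families, a word counted when it lay within 250 bp of the gene's most upstream TSS, and a promoter was bound with a summit within 500 bp. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.

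The rule for named items was fixed before the data were examined. It takes knrl and kni; the 10 peaks with the highest signal and their nearest protein-coding TSS; up to 4 bound members with the strongest peaks and up to 3 unbound members in alphabetical order from each called list and from the gap and pair-rule lists; the 5 genes with most summits; and the 5 words with the lowest p. The lists, words, tests and most alternatives were also fixed then. Alternatives covered the peak list, the replicates used, the threshold, the distances, the flank, the word and the matching. For promoters, gene lists and words, leaving out a replicate meant taking the regions shared by the thresholded lists of the others. These numbered 1878 without replicate 1, 1897 without replicate 2 and 2247 without replicate 3, against 3663 conservative peaks. The kind of list thus changed together with the replicates, and a move there cannot be put down to either alone.

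The procedures were tested on simulated data. With 3663 random summits no word of 7 bases passed, and after the Knirps word was placed in 200 windows it ranked first, with 5 words passing. Over 460 gene list tests on random summits, 3.70% had a raw permutation p under 0.05 and 1 passed after adjustment. These summits were spread evenly along each arm, unlike the real ones. The check therefore does not give the error rate for summits gathered at promoters. A list given summits in 15 members was the 1 list called. When 40.0% of 2647 separate regions were copied into a random list, 40.6% were found to overlap. Random summits gave a promoter p under 0.05 in 2 of 20 permutation runs.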

Results

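Binding sites of a knrl-eGFP fusion were mapped by chromatin immunoprecipitation and sequencing in 3 biological replicates of whole embryos aged 0 to 24 h. The thresholded lists held 2941, 3051 and 3388 peaks in replicates 1, 2 and 3, a mean of 3127 ± 233 (SD, n = 3). The authors' conservative list for the whole series held 3710 peaks, and its median peak on the chromosome arms was 476 bp wide. The read depth behind these lists is unknown, and the signal values quoted for peaks are the authors' own.

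The replicates shared most of their regions, with replicate 3 standing apart. Of the peaks of replicate 1, 85.3% overlapped a peak of replicate 2 and 72.0% a peak of replicate 3. For replicate 2 the shares were 82.6% with replicate 1 and 68.7% with replicate 3, and for replicate 3 they were 62.9% with replicate 1 and 62.7% with replicate 2. Random placements gave at most 2.48% in any of these 6 comparisons (permutation p = 0.0198 in each, the smallest that 100 placements can give). The placements were spread evenly along each arm, whereas most peaks of every list lay at promoters. The p therefore cannot tell agreement on regions from a shared place at promoters. Merging the 3 lists gave 4071 regions, of which 1733 had a peak in all 3 replicates, 828 in 2 and 1510 in 1. Replicate 3 alone held 969 of the latter, against 224 for replicate 1 and 317 for replicate 2. Across conservative peaks, the signal of the strongest overlapping ranked peak had a Spearman correlation of 0.942 between replicates 1 and 2, 0.702 between 1 and 3 and 0.655 between 2 and 3. Pearson correlations of the log signal were 0.957, 0.712 and 0.668. These are correlations across peaks, which are not independent replicates, so no p is given. The conservative list was itself selected by IDR, for ranks that repeat between lists, which can raise these correlations. Which replicates it compares is not given, so the selection may have raised them more for some pairs than for others.

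Most summits of the knrl-eGFP libraries lay at gene promoters. In the conservative list, 3070 of 3663 summits (83.8%, 95% Wilson interval 82.6 to 85.0) were within 500 bp of a TSS, against 13.6% of randomly placed summits, a ratio of 6.17 (permutation p = 0.002, the smallest that 1000 placements can give). The share was 86.6% ± 1.76 (SD, n = 3) in the replicate lists. The median distance to a protein-coding TSS was 85 bp. Introns held 6.69% of summits against 39.6% of random positions, and intergenic sequence held 6.44% against 27.1%. Coding exons held 1.69% against 13.9%, 3' UTRs 0.983% against 4.43%, and 5' UTRs beyond the promoter windows 0.218% against 0.610%. Exons of non-coding genes held 0.164% against 0.786%. Each of these classes was below random placement (permutation p of 0.004 for 5' UTRs and 0.002 for the others). The classes do not overlap and cover all summits, so the excess at promoters by itself lowers the other classes as a group. These tests therefore cannot tell whether any class was avoided. The shares among summits outside promoters were not tested.

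**Figure D1:**
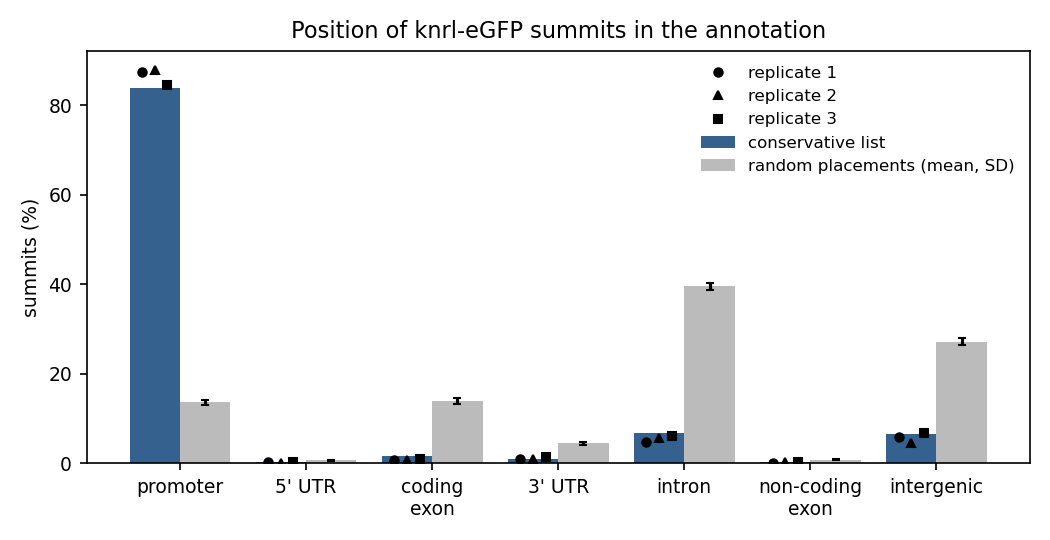
Share of summits (%, vertical axis) in each annotation class for the conservative list (blue bars), the 3 replicate lists (points) and 1000 random placements (grey bars, mean and SD). Promoters hold 83.8% of conservative summits against 13.6% of random ones, and all other classes lie below random placement. The classes do not overlap, so the promoter share by itself lowers the others as a group.

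The strongest peaks were at promoters, among them those of Rpn6 and RpL32. All 10 peaks with the highest signal, from 2713 to 6173, were promoter peaks. The strongest (2R, 21501652 to 21502261, signal 6173) had its summit 107 bp from a TSS of MESK2. The next were beside Rpn6, a proteasome subunit gene (2R, 14752136 to 14752636, signal 4559), and Mic26-27 (3R, 16146534 to 16147175, signal 4542). The peak at RpL32, a ribosomal protein gene (3R, 30046022 to 30046533), had a signal of 3870, and that at RhoGAP93B (3R, 21097684 to 21098163) a signal of 3725. The other 5 had CG11857, CG15160, mi, CG8613 and jagn as their nearest genes, with summits 13 to 98 bp from the TSS. None of the 10 had the Knirps word TAGAGCA within 100 bp of its summit, but only 1.75% of all conservative summits had it. The word ATCGATA, first in the scan described below, was at 5 of the 10. The genes with most summits were Ptp61F, a tyrosine phosphatase gene with 8, EcR, the ecdysone receptor gene, and p with 7 each, and CG8032 and Roc2 with 6 each. The gene CG8032 lies within p, so these 2 share summits. The promoter share rose with signal. It was 97.5% (96.2 to 98.4) among the 733 strongest peaks and 63.5% (60.0 to 66.9) among the 732 weakest (Spearman correlation 0.302 across 3663 peaks, permutation p = 1e-05, the smallest that 100000 permutations can give).

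Genes for ribosomal proteins and for the cell cycle were bound more often than genes of their length, and chemoreceptor genes less often. Summits fell in or near 5569 of 13945 protein-coding genes (39.9%), a median of 2 genes per summit, so a summit is often counted for a neighbouring gene as well. Of 92 ribosomal protein genes 64 were bound (69.6%, 59.5 to 78.0), against 31.0 in matched random lists, a ratio of 2.06 (permutation p = 0.0002, the smallest that 10000 lists can give, adjusted p = 0.0023). The replicate lists gave 64.7 ± 6.43 bound genes (SD, n = 3), above random in 3 of 3. The strongest peaks were those of RpL32, RpS13 (signal 2703), RpS7 (2047) and RpL26 (2001), whereas RpL10, RpL10Aa and RpL13A had none. The peak of RpS13 was nearest to the TSS of Pp2A-29B.

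Of 24 cell cycle and replication genes 19 were bound against 10.8 in random lists, a ratio of 1.75 (permutation p = 0.002, adjusted p = 0.0153, above random in 3 of 3 replicates). Their strongest peaks were at twe (signal 2067), a Cdc25 phosphatase gene, Mcm5 (1481), a helicase subunit gene, geminin (991) and Cdk2 (958). The peaks of twe and Mcm5 were nearest to the TSSs of EndoGI and Art1. The members CycB3, CycE and Mcm2 had none. This call was lost with a gene margin of 10 kb (adjusted permutation p = 0.092), within 1 kb of a TSS (0.0859) and with summits given to the nearest TSS (0.0567).

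Among 230 chemoreceptor and odorant-binding genes, 29 were bound (12.6%) against 85.4 in random lists, a ratio of 0.340 (permutation p = 0.0002, adjusted p = 0.0023, below random in 3 of 3 replicates). When each replicate was left out in turn, the regions shared by the others gave ratios of 0.220 to 0.270, and regions of all 3 gave 0.214. The strongest peaks counted for this list were at promoters of neighbouring genes: that of Ir93a (signal 1220) lay 5 bp from the TSS of RpS30, that of Obp73a (667) at Ogdh, that of Obp46a (629) at RNaseZ and that of Obp59a (627) at robo1. Gr10a, Gr10b and Gr21a had no peak. Some members are neighbours: on X, Gr10b ends at 11413190 and Gr10a starts at 11413467. The random lists did not keep neighbours together, so the permutation p treats such members as independent.

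**Figure D2:**
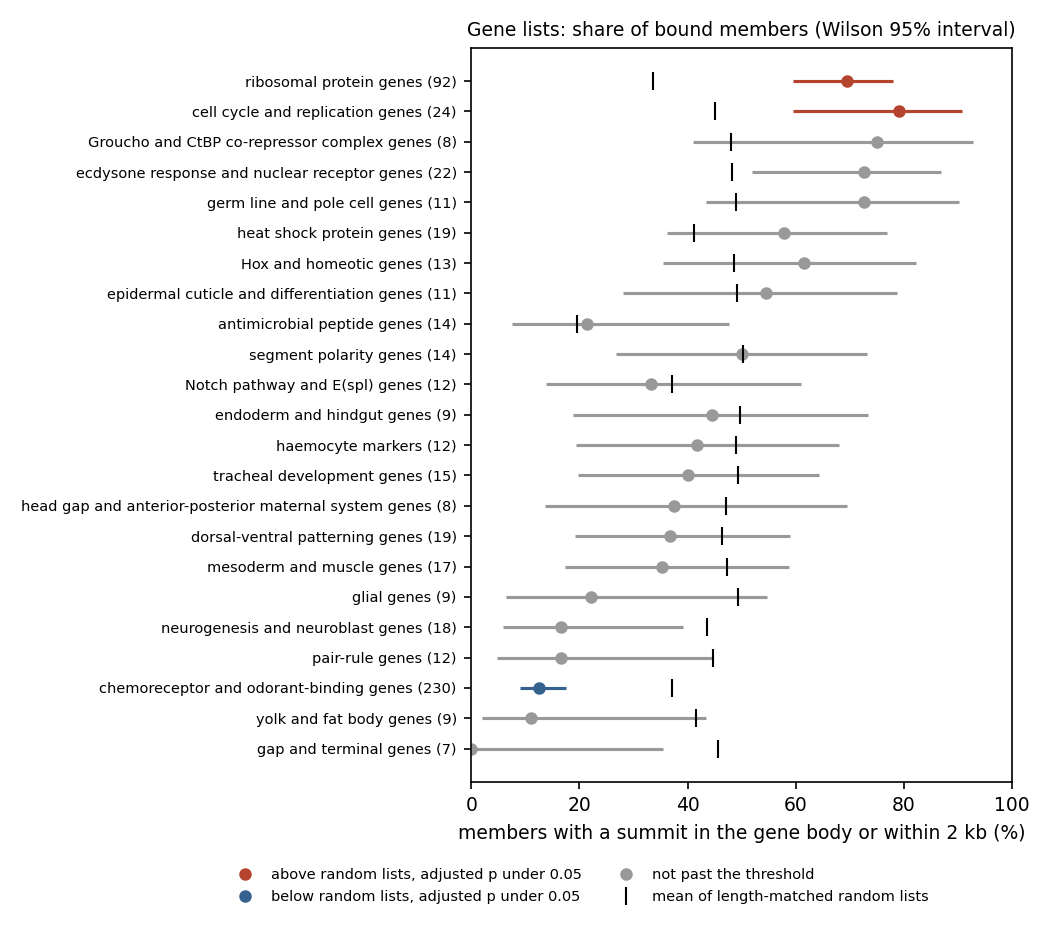
Share of members with a summit in the gene body or within 2 kb (%, horizontal axis) for 23 gene lists, with the number of members in brackets, 95% Wilson intervals as lines and the mean of length-matched random lists as black ticks. Ribosomal protein genes (69.6%) and cell cycle and replication genes (79.2%) are above random lists, and chemoreceptor and odorant-binding genes (12.6%) below.

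The segmentation genes among which Knirps acts were not called. None of the 7 gap and terminal genes was bound, Kr, gt, hb, kni and knrl among them, against 3.20 in random lists (permutation p = 0.0256, adjusted p = 0.132). With a gene margin of 10 kb this list passed, still with 0 bound (permutation, adjusted p = 0.0046), as did the neurogenesis and neuroblast genes (adjusted permutation p = 0.0391). Of 12 pair-rule genes 2 were bound against 5.36 (permutation p = 0.081, adjusted p = 0.266): ftz-f1, with a signal of 481 at its own promoter, and sob, with an intergenic peak of signal 104. The pair-rule genes drm, eve and ftz had no peak. The gene knrl (3L, 20597141 to 20620659) had 4 thresholded peaks within 2 kb in replicate 2 and 0 in replicates 1 and 3 and in the conservative list. Among its 38 ranked peaks within 2 kb in the conservative list's ranked parent, the highest −log10 IDR was 1.89, short of the threshold of 2. The gene kni (3L, 20692330 to 20695378) had no thresholded peak within 10 kb in any of these lists.

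The remaining lists did not pass after adjustment. A raw permutation p under 0.05 was found for 6 of the 23 lists in all, the others being neurogenesis and neuroblast genes (3 of 18 bound, ratio 0.382, adjusted p = 0.132, with ratios of 0.168 to 0.375 without each replicate in turn) and ecdysone response and nuclear receptor genes (16 of 22, ratio 1.51, adjusted p = 0.136). Ratios above 1 were found for Groucho and CtBP co-repressor genes (6 of 8 bound), germ line genes (8 of 11), heat shock protein genes (11 of 19), Hox genes (8 of 13), epidermal genes (6 of 11) and antimicrobial peptide genes (3 of 14). Ratios below 1 were found for segment polarity genes (7 of 14), Notch pathway genes (4 of 12), endoderm and hindgut genes (4 of 9), haemocyte markers (5 of 12), tracheal genes (6 of 15), head gap and maternal genes (3 of 8), dorsal-ventral genes (7 of 19), mesoderm and muscle genes (6 of 17), glial genes (2 of 9) and yolk and fat body genes (1 of 9). Several of these ratios moved by more than 1.5 times from the conservative list to the regions shared by only 2 replicates. In the regions shared by replicates 1 and 2, dorsal-ventral genes were at 0.151, against 0.794 in the conservative list, and passed (adjusted permutation p = 0.0391). In those regions segment polarity genes were at 0.548 against 0.994, haemocyte markers at 0.429 against 0.852 and endoderm and hindgut genes at 0.554 against 0.894. Glial genes were at 0.284 against 0.451 and pair-rule genes at 0.238 against 0.373. Apart from dorsal-ventral genes, none of these lists passed. Yolk and fat body genes were at 0 without replicate 1 or 2, against 0.267, and did not pass. Regions of all 3 replicates, with none left out, also gave lower ratios, none of which passed. They were 0.181 for dorsal-ventral, 0.650 for segment polarity, 0.522 for haemocyte and 0.656 for endoderm and hindgut genes. Glial genes were at 0.343 there, pair-rule genes at 0.285 and yolk and fat body genes at 0. These moves thus cannot be put down to the replicate left out alone. The 3 sets that leave out a replicate are of the same kind, yet some ratios differed among them (not tested). Without replicates 1 and 2 in turn they were 0.4999 and 0.987 for dorsal-ventral and 0.812 and 0.990 for segment polarity genes. Haemocyte markers were at 0.737 and 0.727. Endoderm and hindgut genes (0.620 and 0.612) and glial genes (0.323 and 0.319) differed less. Regions of all 3 replicates are also shared by replicates 1 and 2, so they cannot settle this.

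The Knirps word was no more frequent at summits than beside them. TAGAGCA lay within 100 bp of 64 of 3663 summits (1.75%) and in 68 flank windows (1.86%), a ratio of 0.941 (exact McNemar p = 0.793, adjusted p = 0.793). The exact 95% interval of the ratio of centre-only to flank-only peaks was 0.656 to 1.35. The replicate lists gave 1.81% ± 0.297 at summits and 2.03% ± 0.235 in flanks (SD, n = 3), although the word was higher at summits in 2 of 3. The share of peaks with the word was 2.59% (1.67 to 4.01) among the strongest 733 peaks and 2.32% among the weakest 732 (Spearman correlation 0.00997, permutation p = 0.548). In the parts of the list between these it was 1.64%, 0.820% (0.376 to 1.78) and 1.36%, from stronger to weaker. A rank correlation would not show such a fall and rise, which was not tested. Over 2 alternatives the correlation reached at most 0.0327, and neither passed the threshold. With the shorter word AGAGCA the ratio was 0.725, lower at summits (exact McNemar, adjusted p = 1.78e-05). The flanks were richer in G and C (45.4% against 39.4% at summits). AGAGCA was not set against windows matched on this content, so its lower share may reflect base composition.

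Words of core promoter factors were frequent at summits. Most summits lay at promoters and the flanks were not matched on distance to a TSS. The ratios for these words therefore include what a position at promoters alone would give. The DREF word TATCGATA, the recognition site of a factor of housekeeping promoters, was found at 22.0% of summits and in 0.546% of flanks, a ratio of 40.4 (exact McNemar, adjusted p = 1.09e-211). The word GGTCACAC of M1BP, another factor of such promoters, was found at 6.96% against 0.628%, a ratio of 11.1 (exact test, adjusted p = 5.04e-50). Both were higher at summits in 3 of 3 replicate lists. Over the 12 alternatives the ratio ran from 26.8 to 79.1 for TATCGATA, with 69.1 without replicate 2, and from 11.1 to 22.6 for GGTCACAC, with 22.6 without replicate 2. The nuclear receptor word AGGTCA was lower at summits, with 3.33% against 6.25% (exact test, adjusted p = 6.71e-09). The E-box CAGCTG was at 12.9% against 10.9% (exact test, adjusted p = 0.0131), the homeodomain word TAATTA at 13.8% against 8.93% (adjusted p = 1.42e-10), the Grainyhead word AACCGGTT at 0.355% against 0.0819% (adjusted p = 0.0273) and the Zelda word CAGGTAG at 0.764% against 1.58% (adjusted p = 0.00253). In regions shared by 2 replicates, leaving out each in turn, the ratio for CAGGTAG ran from 0.233 to 0.367, against 0.483 in the conservative list. The ratio for AACCGGTT there ran from 7 to 10, against 4.33, passing only without replicate 2. These ratios rest on few peaks: in the conservative list AACCGGTT was at 13 summits and in 3 flanks (centre-only to flank-only exact interval 1.19 to 23.7). Regions of all 3 replicates, with none left out, gave 0.207 for CAGGTAG and 7 for AACCGGTT. The GAGA factor word GAGAGAG did not pass, with 2.51% against 2.92% (exact test, adjusted p = 0.353). It passed, lower at summits, in regions shared by 2 replicates, at ratios of 0.544 to 0.627. It also passed in regions of all 3 replicates, at 0.491. The calls for CAGCTG and AACCGGTT were each lost in 8 alternatives, among them the flank on the other side of the peak (exact test, adjusted p = 0.0508 and 0.215). Centre windows averaged 39.4% G and C and flanks 45.4%. Against random windows matched on this content the calls for TAATTA, AACCGGTT and CAGGTAG were lost (exact McNemar, adjusted p = 0.554, 0.785 and 1), while the ratio for CAGCTG was higher, at 1.79 (adjusted p = 4.27e-16).

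**Figure D3:**
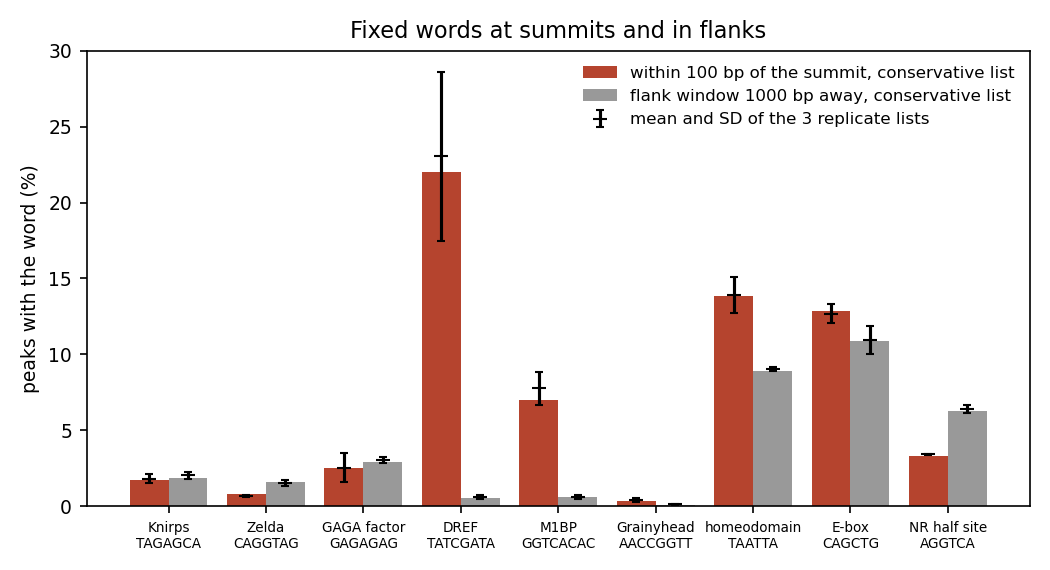
Share of peaks with each fixed word (%, vertical axis) within 100 bp of the summit (red) and in the flank window (grey) of the conservative list, with the mean and SD of the 3 replicate lists in black. TATCGATA is at 22.0% of summits against 0.546% of flanks, and TAGAGCA at 1.75% against 1.86%.

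In the scan of all 8192 words of 7 bases, the word ATCGATA came first. It was at 38.8% of summits and in 2.78% of flanks, with 1381 peaks having it at the centre only and 61 in the flank only. In the replicate lists it was at 40.6% ± 8.83 of summits (SD, n = 3). Replicate 3 had it least often: within 50 bp of the summit it was at 20.8% of peaks there, against 33.8% in replicate 1 and 34.7% in replicate 2. The next 4, CTATCGA (27.6% against 2.07%), ACTATCG (19.7% against 1.45%), ATATCGA (20.1% against 2.40%) and TCGATAA (20.1% against 2.78%), overlap the same sequence. After adjustment 1063 words were higher and 2034 lower at summits, which includes the difference in base composition. Against windows matched on G and C content 764 were higher and 898 lower, with ATCGATA again first. Neither set of windows was matched on distance to a TSS. In the 593 peaks farther than 500 bp from a TSS, ATCGATA was at 10.8% of summits and in 3.20% of flanks. That ratio was 3.37, against 13.9 in the whole list. Chosen after the scan, the share with ATCGATA was set against peak signal. It was 64.5% (61.0 to 67.9) among the 733 strongest peaks and 11.1% (8.99 to 13.5) among the 732 weakest (Spearman correlation 0.404, permutation p = 1e-05).

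**Figure D4:**
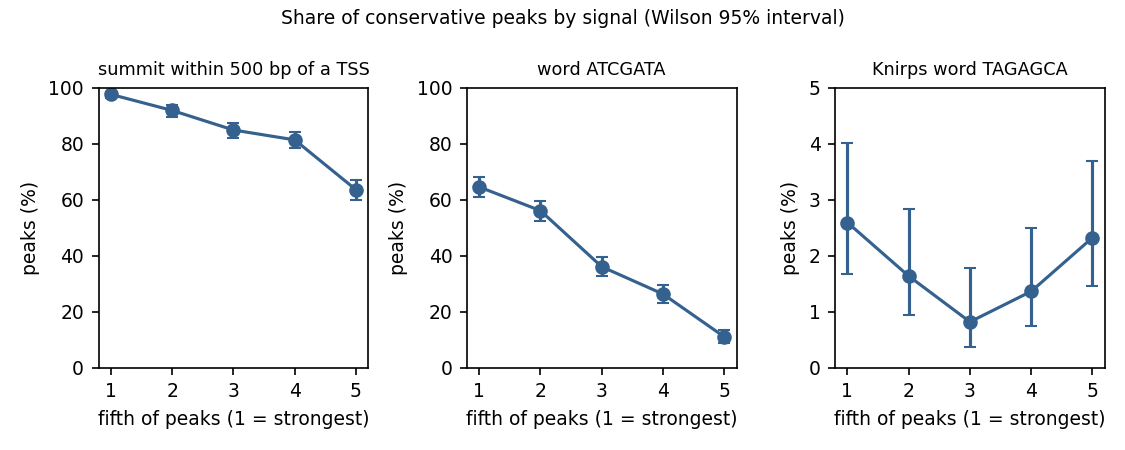
Share of conservative peaks (%, vertical axes with different ranges) that are promoter peaks, that have ATCGATA and that have the Knirps word, in 5 equal parts of the list from the strongest (1) to the weakest (5) signal, with 95% Wilson intervals. The promoter share goes from 97.5% to 63.5% and the ATCGATA share from 64.5% to 11.1%. The Knirps word is at 2.59%, 1.64%, 0.820%, 1.36% and 2.32%, from the strongest part to the weakest.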

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

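Peaks outside the analysed arms and peaks missing from the thresholded lists were counted because no comparison used them. With 3 samples, no test for an outlying sample was made. On the Y chromosome and on unplaced sequences there were 66 peaks in replicate 1, 21 in replicate 2, 6 in replicate 3 and 47 in the conservative list. Of these, 1 in replicate 1 and 1 in the conservative list were on Y. The ranked lists held peaks that met the IDR of 0.01 but were not in the thresholded lists. These numbered 134 in replicate 1, 107 in replicate 2, 124 in replicate 3 and 158 for the conservative list. Of the 112 such conservative peaks on the arms, 66.1% were promoter peaks. The rule by which they were left out is not given in the sources used here.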

How the results depend on the processing

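Alternatives at an IDR of 0.001, on the peaks of above-median signal, on 1 summit per region and the word scan on windows matched on G and C content were chosen after seeing the data. An IDR of 0.01 removed no peak, so it tested nothing, although it is counted in the totals below. The promoter share was above random placement in all 12 alternatives, at 77.2% to 93.7%. Replicate overlap was above random placement in all 7, at 58.3% to 95.7%, the latter against ranked lists, where random placement gave 44.2%. These placements were not confined to promoters. Ribosomal protein genes (ratios 1.43 to 2.69) and chemoreceptor and odorant-binding genes (0.0975 to 0.656) kept their calls in all 13. At an IDR of 0.001 the mean number of peaks per replicate was 2243. Read depth is unknown, so its effect was not examined. No paired analysis was possible because there is 1 group. Where no cause is named below, the cause was not tested.

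The cell cycle call was lost with a gene margin of 10 kb (ratio 1.32), within 1 kb of a TSS (1.81) and by nearest TSS (2.14), leaving 1 list higher in each. With the 10 kb margin 3 lists were lower, the gap and terminal genes and the neurogenesis genes having joined. In regions shared by the other replicates, leaving out each in turn, 1 to 2 lists were lower, with dorsal-ventral genes joining without replicate 3 (ratio 0.151). Their ratio in regions of all 3 replicates was 0.181, which did not pass. The unmatched Fisher exact test gave 3 lists higher, with ecdysone response and nuclear receptor genes joining. The Knirps word passed only as the shorter AGAGCA, lower at summits (ratio 0.725). That shorter word was not set against windows matched on G and C content. For TAGAGCA the ratio was 1 in regions of all 3 replicates, among peaks of above-median signal and against windows matched on G and C content, 1.02 at an IDR of 0.001, 1.05 with the higher-coordinate flank and 0.854 to 1.02 without each replicate in turn, none past the threshold. The E-box call was lost in 8 of 12 alternatives and the Grainyhead call in 8, while the GAGA factor word became lower at summits in 6 (ratios 0.443 to 0.627).

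The following ratios lay on the other side of 1 from the value reported, and neither value passed the threshold unless stated. With the longest other series list they were 1.53 for head gap and maternal genes, 1.42 for tracheal genes, 1.29 for Notch pathway genes and 1.05 for the GAGA factor word. In regions of all 3 replicates they were 0.768 for Hox genes, 1.04 for Notch pathway genes and 0.785 for heat shock protein genes. Among peaks of above-median signal they were 0.499 for Hox genes, 0.560 for epidermal genes and 0.938 for heat shock protein genes. With the 10 kb margin they were 1.05 for tracheal, 1.11 for Notch pathway, 0.893 for epidermal and 1.24 for glial genes. Within 1 kb of a TSS they were 1.09 for head gap and maternal, 0.992 for Hox, 1.06 for tracheal, 1.02 for Notch pathway, 0.884 for ecdysone response and 0.561 for antimicrobial peptide genes. By nearest TSS they were 2.02 for head gap and maternal, 1.04 for pair-rule, 1.09 for dorsal-ventral, 1.85 for tracheal, 1.04 for Notch pathway and 0.343 for antimicrobial peptide genes. Without matching they were 1.25 for segment polarity, 1.00 for tracheal, 1.11 for endoderm and hindgut, 1.04 for haemocyte and 0.537 for antimicrobial peptide genes. Without each replicate in turn the ratios ranged from 0.705 to 1.09 for Hox, 0.784 to 1.00 for tracheal, 0.966 to 1.10 for antimicrobial peptide and 0.792 to 1.30 for heat shock protein genes. Against windows matched on G and C content they were 1 for the GAGA factor word and 0.942 for the homeodomain word, whose reported value had passed.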

Other observations

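Other gene families, chosen after the strongest peaks had been seen, were compared with length-matched random lists by permutation with adjustment over 6 families. Mitochondrial ribosomal protein genes were bound in 50 of 73 cases, a ratio of 2.36 (permutation, adjusted p = 0.0006). Proteasome subunit genes were bound in 28 of 48, a ratio of 1.65 (permutation, adjusted p = 0.0036), and Mediator subunit genes in 15 of 25, a ratio of 1.61 (adjusted p = 0.0432). The Mediator call held in 4 of 9 other peak sets, the proteasome call in 8 and the mitochondrial call in 9. Cuticle protein genes were bound in 11 of 117, a ratio of 0.301 (permutation, adjusted p = 0.0006), a call that held in all 9. Translation initiation factor genes (25 of 44, permutation, adjusted p = 0.071) and aminoacyl-tRNA synthetase genes (16 of 32, adjusted p = 0.708) did not pass.

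The pattern that a biologist would most want to follow up is that ATCGATA is more frequent at the summits of a Knirps relative than beside them, at 38.8% of them, while the Knirps word is not, at 64 summits and in 68 flanks. The test on housekeeping families was chosen after the pattern and the rates over all promoters had been seen, and the others were set before their results were seen. Within 7 families of housekeeping function, binding differed by word, which promoters bound alike whatever their sequence would not give. This does not settle the cause, since most of these families were chosen after the strongest peaks had been seen. Whether members with the word differ from the others in another way was not examined. The word TATCGATA was fixed beforehand, but it contains ATCGATA and had already been found frequent at these summits. Promoters with TATCGATA were bound in 72 of 84 cases (85.7%) and those without it in 93 of 251 (37.1%). The Mantel-Haenszel odds ratio was 11.3 (95% interval 5.65 to 22.7). Over all promoters, 64.7% of those with ATCGATA and no M1BP word were bound, 28.7% with the M1BP word and no ATCGATA, 80.3% with both and 13.3% with neither. These rates decide nothing, since ATCGATA was chosen from the same peaks. Whether the tagged protein reached some sites through its own word stays open, since in the 593 peaks farther than 500 bp from a TSS the ratio of centre-only to flank-only peaks was 1.5 with an exact interval of 0.477 to 5.12. Over all promoters, 25.5% of those with the Knirps word and 25.0% of those without it were bound, a ratio of 1.02 (95% interval 0.878 to 1.18), which leaves room for a part of the sites. A candidate explanation that also stays open is chromatin of another protein, through a mislabelled sample or an off-target antibody: in the strongest 733 peaks the Knirps word had a ratio of 1.06 (exact interval 0.524 to 2.13), while ATCGATA lay near summits in each replicate list. Recruitment of the fusion by a protein that binds ATCGATA was not tested and would give the same values, so no binding by knrl through its own word is shown or excluded here.

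Another pattern is the 1081 peaks of replicate 3 that overlap no peak of the other replicates. The tests were set before the results were seen, except the median over all 1081 peaks and the M1BP and Knirps word values. Their overlapping ranked peaks had a median signal percentile of 91.1 in replicate 1 (bootstrap interval 90.3 to 92.2) and 91.9 in replicate 2, against 63.5 and 64.1 for randomly placed peaks, which may mean that the other replicates hold the same regions under their threshold. Counting the peaks with no counterpart as 0 lowered the medians to 84.6 and 88.2, and the thresholded lists would start at percentiles of 97.7 and 96.9, so this is open for a part of the peaks. Background of replicate 3 alone cannot be told apart from binding either: ATCGATA was at 3.61% of these summits, a centre-only to flank-only ratio of 2.38 (exact interval 1.29 to 4.56, exact p = 0.00384) against 31.1 in peaks shared with both other replicates, and the interval is too wide for the bound of 2 set for it. The M1BP word was at 9.62% of these summits and 0.648% of their flanks, a centre-only to flank-only ratio of 17.2 (exact interval 7.62 to 47.9), against 15.3 in the shared peaks, where it was at 8.63% of summits. The Knirps word was at 10 of the summits of replicate 3 alone and in 24 of their flanks (centre-only to flank-only exact interval 0.178 to 0.904). Of these peaks 71.6% were promoter peaks, so they are not random positions, but promoter chromatin enriched without the protein would look alike.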
